A study of Paraburkholderia busanensis with 6 samples.

How the data were processed

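RNA-seq libraries of *P. busanensis* P39 grown alone (3 biological replicates) and exposed to *C. scovillei* fungal material (3 biological replicates) were compared. Per the labels' protocols, total RNA was sequenced paired-end on an Illumina HiSeq instrument. DESeq2 is named in the submitters' processing notes with no role or version. The aligner, the counting program, strand handling and the genome build are not given in the sources used here, so coordinates are those of the files on contig 1 and contig 2. No reference genome was used.

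Raw counts per gene were deposited for 6805 genes, per the file headers, and all tests were run on them. The deposited FPKM values equal the counts scaled by gene span and library total, to within 0.1% for 100% of nonzero values checked. The deposited RLE-normalised signal holds the 5256 genes above 0 in all 6 libraries. Multiplying by a size factor per library, from 0.408 to 2.89, gave whole reads to within 0.01 that equalled the deposited count in 100% of values. Of the gene lengths 98.9% were multiples of 3, so they are coding lengths. A total of 88 rows had no symbol or product and held 0.0231% to 0.0698% of the counts of a library.

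Genes were filtered with filterByExpr, scaled with TMM and tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) with group as the only term, two-sided, and p values were adjusted by Benjamini-Hochberg. TMM factors ran from 0.358 to 2.49. A gene changed at an adjusted p under 0.05, and a 2-fold change also needed an absolute log2 fold change of 1. The common dispersion was 0.152. A count of 3, the floor, corresponded to 0.0662 to 0.476 CPM. Replicate numbers were not used as pairs, since the labels state no pairing, and a replicate block was an alternative. After removal of the group mean, correlations of libraries with the same number were 0.106, -0.1 and 0.0253. The highest with another number were 0.108, 0.156 and 0.00197, so these values do not settle whether the libraries were paired.

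The comparison, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except those called chosen later. The rule named the 10 highest and 10 lowest log2 fold changes among passing genes with a mean CPM of at least 20, no overlap between groups and a product that was not only hypothetical. It also named up to 3 passing members of each list with a mean CPM of at least 20 (or, if none passed both, the member with the smallest p), and the 3 genes with the most counts per group. It gave 97 genes, of which 95 passed. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. Lists were matched by symbol or product, and 342 memberships that matched by symbol or word only were left out in an alternative chosen later.

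The method was tested on simulated data for this comparison, with counts for 5222 genes. It recovered 25 of 100 genes changed 2-fold and 97 of 100 changed 4-fold, and called 4 unchanged genes. The changed genes all had a mean CPM of at least 20. A list raised 2-fold was called and 0 of the other lists were. Genes were drawn independently, so the simulation does not show how correlation between genes affects list calls.

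Alternatives were RLE and upper-quartile factors, library totals, removal of the 10 genes with the most counts, no filter, a mean CPM of at least 20, DESeq2 1.42.0, limma-voom, a replicate block, each library left out, limma on log2 FPKM and on log2 RLE counts, and glmTreat against 1.5-fold. The planned removal of ribosomal RNA genes had none to remove. Removal of *ssrA*, thinning of counts, reads recovered from the RLE values and the shortened lists were added after the data were seen. Intervals of medians came from 2000 bootstrap draws of genes, taken as independent, and do not cover variation between libraries. Figures were drawn with matplotlib 3.10.9.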

Results

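Total RNA of the bacterium *Paraburkholderia busanensis* P39 was sequenced after growth alone and after exposure to biomass of the fungus *Colletotrichum scovillei* KC05. Each condition had 3 biological replicates, which gave 6 libraries. The question was which bacterial transcripts respond to the fungal material. The count table held 6805 genes, 3914 on contig 1 and 2891 on contig 2, of which 2372 were named only as hypothetical proteins. Total counts were 12877457, 17606920 and 14596729 in alone replicates 1 to 3, and 18257976, 17794943 and 15835350 in fungal biomass replicates 1 to 3. The batch entry in the labels was the same for all libraries of a condition and differed between the conditions, so a batch effect cannot be told apart from the fungal biomass.

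Most counts of the alone libraries fell on *ssrA* (P39_1_01383, contig 1, 1606321 to 1606690), the gene of transfer-messenger RNA, which rescues stalled ribosomes. It took 64.8% ± 13.4 of the counts in the alone libraries and 32.3% ± 12.3 in the fungal biomass libraries (mean ± SD, n = 3). By library the share was 51.5%, 78.2% and 64.7% alone, and 19.5%, 33.3% and 44.0% with fungal biomass. The widest of the 95% Clopper-Pearson intervals, for alone replicate 1, ran from 51.42% to 51.48%, and such intervals cover counting error only. The groups did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. Counts outside *ssrA* came to 6251884, 3836710 and 5148483 alone and to 14702836, 11876317 and 8861442 with fungal biomass. The 10 genes with the most counts took 72.1% ± 11.7 alone and 40.5% ± 11.5 with fungal biomass. No row of the table named a ribosomal RNA gene.

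**Figure D1:**
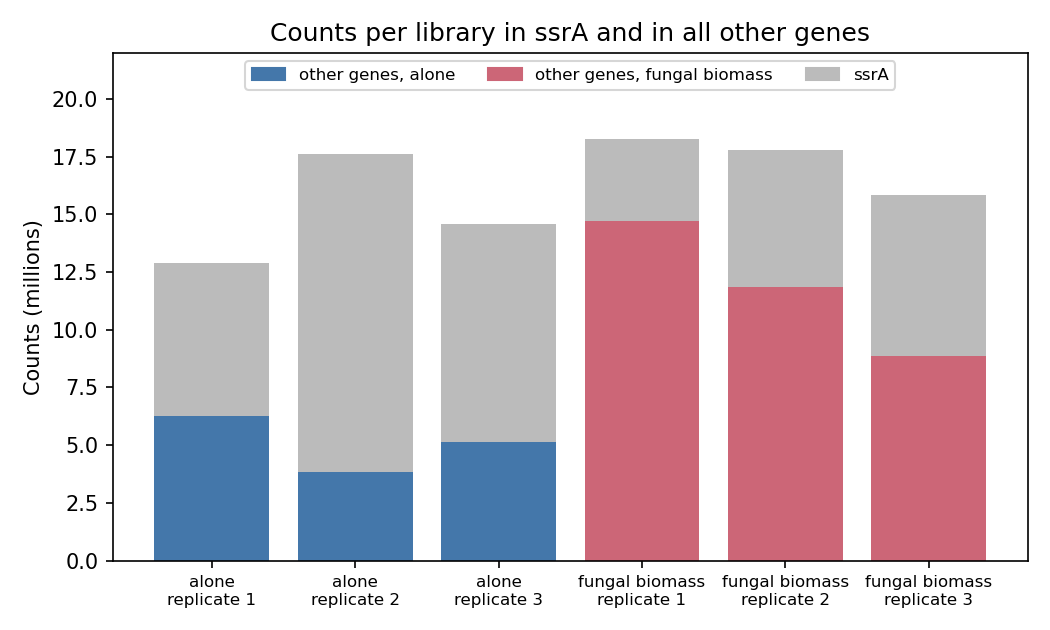
Counts for each of the 6 libraries, split into ssrA (grey) and all other genes (blue, alone; red, fungal biomass). In the alone libraries 51.5% to 78.2% of the counts fell on ssrA, against 19.5% to 44.0% with fungal biomass.

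The conditions separated along the first principal component, but alone replicate 1 correlated with fungal biomass replicate 3 at least as well as with alone replicate 2. Spearman correlations of log2 CPM across genes were 0.914 to 0.937 within the alone group, 0.943 to 0.963 within the fungal biomass group and 0.806 to 0.921 between groups. The correlation of alone replicate 1 was 0.921 with fungal biomass replicate 3 and 0.914 with alone replicate 2. The first principal component held 58.1% of the variance and placed the alone libraries at -17.4, -70.3 and -50.2, and the fungal biomass libraries at 54.1, 51.5 and 32.3.

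With fungal biomass, the glycerol genes *glpD* and *glpK*, the multidrug resistance gene *bmr3_2* with its neighbouring regulator gene *ttgW*, the histidine ammonia-lyase gene *hutH_3* and the cytochrome *bd* gene *cydA_2* rose. The flagellar genes *fliK* and *flgK*, the polyamine import genes *potA_1* and *potD*, and *boxA*, *bfr*, *phaA* and *phaB* fell. The *flhD* copy on contig 2 fell as well, but the copy on contig 1 did not pass. Chemotaxis genes had 6 higher and 5 lower of 42 tested, where 26.7% of all tested genes changed. Of 111 tested genes of amino acid biosynthesis 26 rose, 6 fell and 79 did not pass, and the list did not move with an estimated correlation (adjusted p = 0.779). The neighbouring ribosomal protein genes *rplB*, *rplC* and *rplD* fell. Of 9 tested genes listed by name for breakdown of chitin or fungal walls, 6 did not pass.

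Of 5518 genes tested, 1475 changed, 623 higher and 852 lower with fungal biomass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found in 1315 of them, 531 higher and 784 lower. The groups did not overlap in 2413 genes, or 43.7% of those tested. With no difference between the groups, 10% would be the average over all splits of the libraries. Genes vary together between libraries, so the contrast of these shares is no test of chance. On contig 2, 180 genes rose and 402 fell, whereas on contig 1 443 rose and 450 fell. The directions hold relative to the bulk of genes: with library totals in place of TMM scaling the median log2 fold change of all genes shifted by 1.57, and 97.9% of the called genes were then higher, against 42.2% with TMM. The count fell to 874 without alone replicate 2, 809 without alone replicate 3 and 914 without fungal biomass replicate 2.

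The gene *glpD* showed the largest rise among the named genes. Aerobic glycerol-3-phosphate dehydrogenase *glpD* (P39_1_01720, contig 1, 1978729 to 1980258) rose from 1.79 ± 0.197 to 570.4 ± 144 CPM (mean ± SD, n = 3), a log2 fold change of 8.31 ± 0.40 (SE) with an edgeR adjusted p of 1.37e-07. The next gene, glycerol kinase *glpK* (P39_1_01721), rose by a log2 fold change of 5.45 ± 0.58 (SE), from 1.79 ± 1.40 to 73.3 ± 34.7 CPM. The multidrug resistance gene *bmr3_2* (P39_2_01653, contig 2, 1877916 to 1879451) rose from 6.46 ± 1.80 to 627.7 ± 203 CPM, with a log2 fold change of 6.59 and an edgeR adjusted p of 1.42e-06. Its divergent neighbour *ttgW* (P39_2_01654), a putative transcriptional regulator, rose from 7.86 ± 3.48 to 237 ± 86.9 CPM.

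Histidine ammonia-lyase *hutH_3* (P39_1_03734) rose from 6.47 ± 5.78 to 165 ± 73.1 CPM. Its neighbours *mngR* (P39_1_03735) and *hutU_2*, chosen after their values were seen, rose with log2 fold changes of 4.22 and 1.53. The neighbours *hutI* (0.27, edgeR adjusted p = 0.897) and *dmlR_21* (0.24, adjusted p = 0.828) did not pass. Their means of 0.401 and 1.44 CPM leave their direction open. The gene of lysine 6-dehydrogenase *lysDH* (P39_1_00144) rose from 316 ± 65.4 to 4113 ± 258 CPM. The cytochrome *bd* subunit *cydA_2* (P39_2_01619) rose from 20.3 ± 5.60 to 244.6 ± 52.9 CPM, and the gene of its partner subunit, *cydB_2*, named after its value was seen, rose with a log2 fold change of 2.31. A putative oxidoreductase (P39_2_00806) had a log2 fold change of 4.55 (3.87 to 5.74 over its 10 alternatives). It had 12.2, 3.81 and 1.68 CPM alone and 81.5, 248 and 94.4 CPM with fungal biomass. A putative regulator (P39_1_00976) and the azoreductase gene *azoR1_1*, which overlap each other, had log2 fold changes of 6.25 and 3.68. Both varied between replicates, since fungal biomass replicate 1 held 5.58 CPM of the regulator against 77.9 and 190 CPM in the other replicates.

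Among genes that fell, the DevR/DosR-type regulator *devR_1* (P39_2_01951, contig 2, 2245310 to 2245741) dropped from 53.6 ± 29.7 to 2.07 ± 1.58 CPM, a log2 fold change of -4.70 ± 0.67 (SE) with an edgeR adjusted p of 0.00045. Its overlapping neighbour *fnr_2* fell as well, with a log2 fold change of -3.67. Because the counting program and strand handling are not given in the sources used here, values of overlapping genes are uncertain. The genes *devR_1* and *fnr_2* lie on the same strand, so strand handling bears on *fnr_2* only through its overlap with P39_2_01953 on the other strand. The chemotaxis kinase gene *cheA_1* (P39_1_02208) fell from 1951 ± 1272 to 122 ± 123 CPM, and the receptor genes *tar_2* (P39_2_00989) and *tar_3* (P39_2_01124) had log2 fold changes of -3.80 and -3.47. Benzoyl-CoA oxygenase *boxA* (P39_1_01036) fell from 72.9 ± 14.6 to 3.73 ± 1.82 CPM. Of its neighbours, chosen after their values were seen, *boxB* fell, at -2.98, and *boxC* did not pass (0.95, edgeR adjusted p = 0.222). With a mean of only 7.23 CPM the direction of *boxC* stays open. The polyamine import genes *potA_1* (P39_2_00522) and *potD*, which lie side by side, had log2 fold changes of -3.82 and -2.75.

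Further decreases reached several functions. A cysteine--tRNA ligase gene on contig 2, *cysS* (P39_2_01773), had a log2 fold change of -4.38, the 2-aminoethylphosphonate transport gene *phnV* -4.34 and the outer membrane gene *oprM_2* -3.95. The HU-beta gene *hupB_2*, at 279 bp, had a log2 fold change of -3.69. Genes of up to 400 bp with a mean CPM of at least 20 had a median log2 fold change of -0.567, against 0.06 in longer genes, which limits the reading of short genes such as *hupB_2*, *clpS*, *cbpM*, *flhD* and *hpf*. *ssrA* itself had a log2 fold change of -2.67 and an edgeR adjusted p of 0.0141, which did not pass without alone replicate 2 or without fungal biomass replicate 2 (up to 0.0954). Of the other genes with the most counts, the hypothetical genes P39_1_00155 and P39_1_01920 fell, with log2 fold changes of -1.67 and -3.17, though P39_1_00155 did not pass without fungal biomass replicate 2 (adjusted p = 0.0689) or with library totals (-0.07, adjusted p = 0.9). The gene *fnr_1* did not pass (adjusted p = 0.445).

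**Figure D2:**
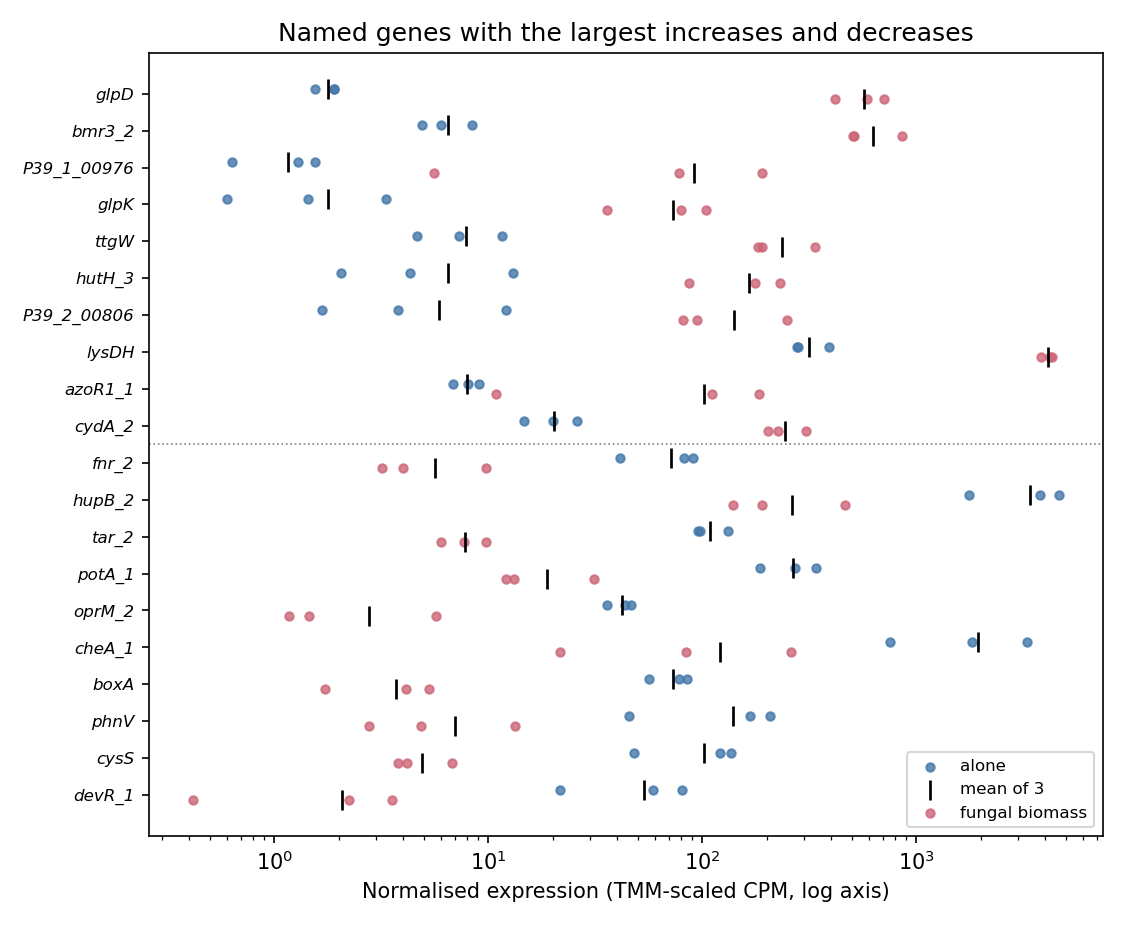
TMM-scaled CPM on a log axis for the 10 named genes with the largest increases (above the dotted line) and the 10 with the largest decreases, with a point per replicate (blue, alone; red, fungal biomass) and a bar at the mean of 3. The glpD libraries lie at 1.56 to 1.90 CPM alone and at 417.7 to 704.7 CPM with fungal biomass.

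The 37 gene lists were fixed before the data were examined, and 36 had enough tested members. Some members had matched by symbol or word only and have other functions. Counts called shortened leave these out, a choice made after the data were seen, and give the members that rose, fell and did not pass. Of all 5518 tested genes 26.7% changed, 623 higher and 852 lower. A list called at a similar share therefore shows nothing particular to its function by its counts alone. Only amino acid biosynthesis moved against all other genes by camera with a preset correlation. Of its 111 tested members 26 rose, 6 fell and 79 did not pass (27 and 7 adjusted over the list alone, shortened 26, 6 and 72), with a median log2 fold change of 0.53 and an adjusted p of 0.0303 (adjusted p = 0.779 with an estimated correlation). Aspartate kinase *lysC* and the secreted chorismate mutase P39_1_01445 rose, with log2 fold changes of 2.17 and 2.05, and the argininosuccinate lyase *argH_1* fell, at -2.18. The call did not pass without alone replicate 1 (adjusted p = 0.128) or without fungal biomass replicate 1 (adjusted p = 0.0505), with replicate number as a block (adjusted p = 0.0605) or with library totals (adjusted p = 0.0548). No list moved with an estimated correlation, and fry, which asks only whether a list's genes move on balance, called 9.

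Of 52 flagellar and motor genes 2 rose, 12 fell and 38 did not pass (2 and 12 adjusted over the list alone; camera adjusted p = 0.102, but 0.0492 without alone replicate 3 and 0.0245 without fungal biomass replicate 3). The *flhD* copy on contig 2 (P39_2_02663), labelled a flagellar transcriptional regulator, fell from 117 ± 40.6 to 17.4 ± 9.02 CPM. The hook-length gene *fliK* fell from 116.7 ± 28.5 to 18.1 ± 8.34 CPM and the hook-associated gene *flgK* from 119 ± 4.87 to 33.1 ± 9.72 CPM. A second *flhD* (P39_1_02213), on contig 1, did not pass (adjusted p = 0.999). Which copy controls the flagellar genes was not tested. After members matched by symbol or word only were left out, which was done after the data were seen, this list moved down (1 rose, 12 fell, 33 did not pass; adjusted p = 0.0128) with the preset correlation but not with an estimated correlation (adjusted p = 0.665). Chemotaxis genes split, with 6 higher, 5 lower and 31 not passing of 42 (6 and 5 adjusted over the list alone; adjusted p = 0.928), and *cheC* (P39_2_00377) and *cheY_1* (P39_2_00378) rose at 2.14 and 1.87. Of 11 members of the pilus list 3 fell and 8 did not pass (3 adjusted over the list alone, camera adjusted p = 0.643). Of the 3, *tadA* (P39_2_00369) is labelled a tRNA deaminase and was left out of the shortened counts (0, 2 and 7). At 1539 bp it is longer than the *tadA* of contig 1 with the same label (P39_1_00003), so its function is uncertain.

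**Figure D3:**
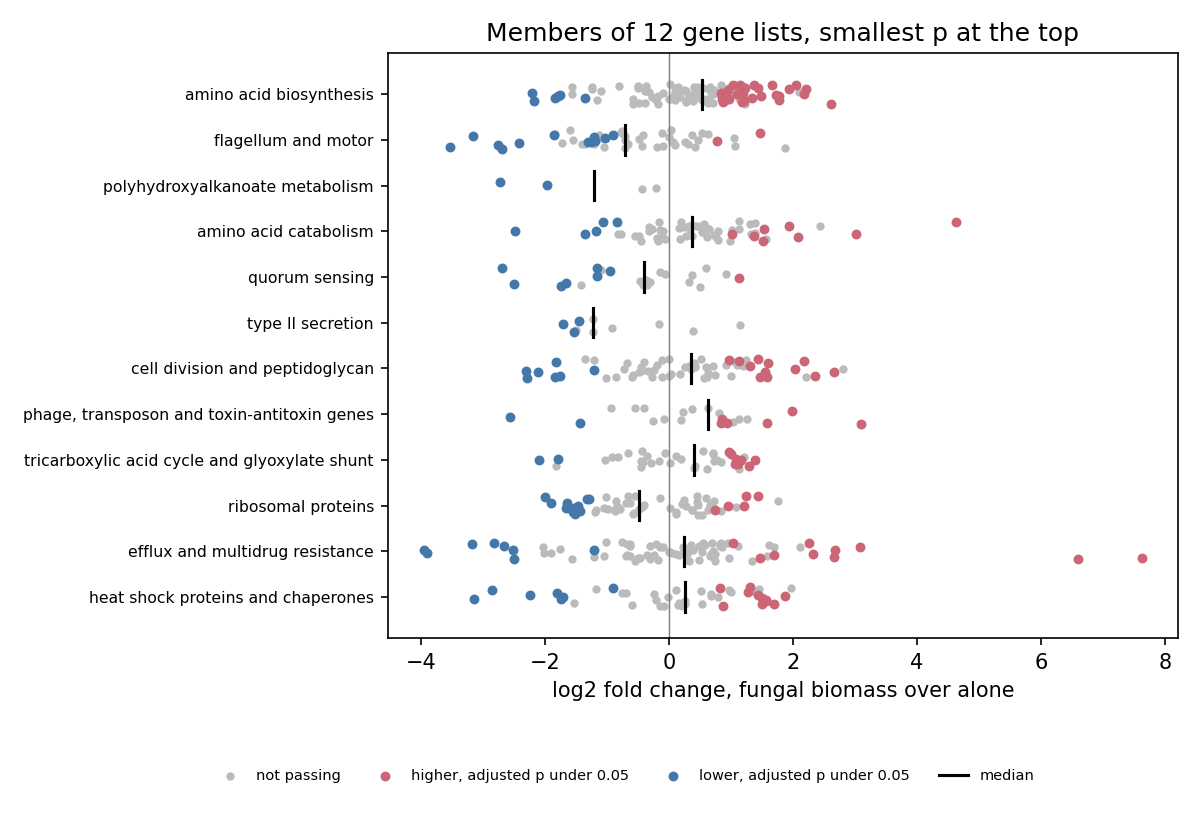
Log2 fold change (fungal biomass over alone) of each tested member of 12 gene lists, with members that rose in red, members that fell in blue and members that did not pass in grey; the black bar is the list median. Amino acid biosynthesis has its median at 0.53 and flagellum and motor at -0.71. With library totals, which shifted the median of all genes by 1.57, the flagellar median turned to 0.92.

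No list of central carbon metabolism passed camera. Of 61 amino acid catabolism genes 8 rose, 5 fell and 48 did not pass (7 and 4 adjusted over the list alone; adjusted p = 0.212, shortened 5, 4 and 25). Among those that fell, at -1.17, was tryptophan 2,3-dioxygenase *kynA*, which did not pass in 4 of 6 fits with a library left out (adjusted p up to 0.189). The polyhydroxyalkanoate list held *phaA* and *phaB*, neighbours that both fell, at -1.97 and -2.72, and 2 genes that did not pass (2 fell adjusted over the list alone; adjusted p = 0.154). In the tricarboxylic acid cycle list 8 rose, 2 fell and 27 did not pass of 37 (8 and 2 adjusted over the list alone; adjusted p = 0.484, shortened 6, 0 and 15), *sdhC* being higher by 1.16. Sugar and polyol genes split into 19 higher, 22 lower and 113 not passing (19 and 22 adjusted over the list alone; adjusted p = 0.736, shortened 17, 14 and 88), with galactonate dehydratase *dgoD_2* higher. Of 34 beta-oxidation genes 2 rose, 5 fell and 27 did not pass (2 and 5 adjusted over the list alone; adjusted p = 0.722, shortened 2, 5 and 23). The acyl-CoA dehydrogenase *mmgC* (P39_1_02939) rose from 44.8 ± 15.1 to 382.6 ± 198 CPM, and *fadB* (P39_1_00495) fell by 1.42 on the log2 scale. Fatty acid synthesis had 5 higher, 5 lower and 20 not passing (5 and 5 adjusted over the list alone; adjusted p = 0.857, shortened 4, 5 and 19), with *accA* and *fabV* higher and *fabG_1* (P39_2_00299) lower.

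No list of nutrient uptake or of breakdown of aromatic compounds passed camera either. Amino acid transport had 6 higher, 15 lower and 64 not passing (5 and 11 adjusted over the list alone; adjusted p = 0.565, shortened 6, 12 and 56), and the putrescine-binding gene *spuD_1* (P39_1_00031) fell from 4418 ± 797 to 1036 ± 455 CPM. In aromatic compound degradation 4 rose, 10 fell and 51 did not pass (4 and 9 adjusted over the list alone; adjusted p = 0.54, shortened 3, 8 and 34), with the dioxygenase component *nagAb* higher at 2.92. Its value ran from 2.5 to 4.67 over its 10 alternatives, and alone replicate 1 held 13.7 CPM against 1.90 and 1.68 CPM in the other alone replicates. Nitrogen assimilation had 1 higher, 2 lower and 15 not passing (1 and 2 adjusted over the list alone; adjusted p = 0.711, shortened 1, 1 and 8), with the carbonic anhydrase gene *cynT* higher. Phosphate starvation had 2 higher, 3 lower and 44 not passing (0 and 3 adjusted over the list alone; adjusted p = 0.95), the glycerol-3-phosphate-binding gene *ugpB* being lower at -1.22. Sulfur assimilation had 2 higher, 3 lower and 27 not passing (2 and 2 adjusted over the list alone; adjusted p = 0.95), with the putative sulfate transporter P39_2_01255 lower at -2.64. Oxalate, formate and C1 metabolism had 2 higher, 2 lower and 22 not passing (0 and 2 adjusted over the list alone; adjusted p = 0.857, shortened 2, 1 and 16), and the formate-dependent purine gene *purT* fell.

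Iron genes had 3 higher, 4 lower and 21 not passing of 28 (2 and 4 adjusted over the list alone, camera adjusted p = 0.857). Bacterioferritin *bfr* fell from 232 ± 12.7 to 49.95 ± 20.4 CPM and the hemin transport gene *hemS* (P39_1_02352) from 54.2 ± 9.43 to 9.81 ± 3.62 CPM, while the ferredoxin *bfd* rose at 2.99 (1.86 to 3.48 over its 10 alternatives), with 243 CPM in fungal biomass replicate 1 against 27.2 and 78.8 CPM in the others. In oxidative stress defence 11 rose, 9 fell and 39 did not pass (11 and 10 adjusted over the list alone; adjusted p = 0.95). The peroxidase gene *yfeX* fell from 504.9 ± 40.5 to 50.1 ± 9.68 CPM, *msrA2* fell at -1.91 and *dps2* rose at 1.76. Of 44 chaperone genes 11 rose, 7 fell and 26 did not pass (13 and 9 adjusted over the list alone; adjusted p = 0.54), with *clpB* (P39_1_00600) higher at 1.87 and *cbpM* and *clpS* lower at -2.85 and -1.71. In universal stress and stationary phase 2 rose, 5 fell and 14 did not pass (2 and 5 adjusted over the list alone; adjusted p = 0.928, shortened 1, 5 and 9), with the stress protein gene P39_2_00014 and the ribosome hibernation gene *hpf* lower at -1.77 and -1.53. Efflux genes had 10 higher, 8 lower and 63 not passing (10 and 8 adjusted over the list alone; adjusted p = 0.54, shortened 9, 8 and 60), including *stp_6* at 3.08. The value of *stp_6* ran from 2.68 to 4.48 over its 10 alternatives, and alone replicate 1 held 31.9 CPM against 6.51 and 4.80 CPM in the other alone replicates.

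Translation and respiration genes changed in part. Of 59 ribosomal protein genes 5 rose, 12 fell and 42 did not pass (5 and 13 adjusted over the list alone; adjusted p = 0.54, shortened 5, 12 and 37). Without fungal biomass replicate 3 the camera adjusted p at the preset correlation was 0.0245. With the estimated correlation of 0.3 and no library left out it was 0.947. The 12 that fell all lie in a single stretch of contig 1 (2314331 to 2325627), which also holds members that did not pass. Among them *rplB*, *rplC* and *rplD* fell at -1.59, -1.54 and -1.64. Translation factors and tRNA synthetases had 16 higher, 20 lower and 82 not passing (20 and 20 adjusted over the list alone; adjusted p = 0.984). Many members had matched by symbol only, and without them 12 rose, 2 fell and 26 did not pass (adjusted p = 0.138). Complex I and ATP synthase had 2 higher and 19 not passing (0 adjusted over the list alone; adjusted p = 0.95, shortened 1, 0 and 18), among them *atpB* at 0.92. Terminal oxidases had 6 higher, 8 lower and 28 not passing (6 and 8 adjusted over the list alone; adjusted p = 0.928, shortened 6, 7 and 24), with *ctaE_2* lower at -1.91. *cydB* was lower at -1.31, but its groups overlapped and it did not pass in 3 fits with a library left out (adjusted p up to 0.117). The list meant for ribosomal RNA held 4 enzymes that modify ribosomal RNA instead, of which 1 rose and 3 did not pass (1 adjusted over the list alone; adjusted p = 0.31). That gene, *rlmB_2*, had a mean of only 0.521 CPM and did not pass in 8 of 10 alternatives (adjusted p up to 0.15).

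The list for chitin and fungal wall degradation had 1 higher, 2 lower and 6 not passing of 9 (1 and 2 adjusted over the list alone, adjusted p = 0.904, shortened 1, 2 and 3). Its member *nagZ* (P39_1_01262), labelled a beta-hexosaminidase, was lower at -1.35. It was matched by name, and whether it acts on chitin or fungal walls was not tested. The protease list had 4 higher, 3 lower and 8 not passing (5 and 3 adjusted over the list alone; adjusted p = 0.711). Of the 3 lower genes *degS_1* and *degS_2* encode sensor kinases (shortened 3, 1 and 6). The metalloprotease *pmbA* was higher at 1.60. Type VI secretion had 3 higher, 2 lower and 11 not passing (3 and 2 adjusted over the list alone; adjusted p = 0.736, shortened 3, 2 and 10), and the near-identical names *vgrG1_1*, *vgrG1_4* and *vgrG1_6* mark paralogs, whose shared reads were not separated here. Type II secretion had 3 lower and 7 not passing (3 adjusted over the list alone; adjusted p = 0.31, shortened 0, 2 and 4), with *xcpT* at -1.45. Type III secretion had too few members to test, and its match *hrcA*, a heat-shock repressor, did not pass (adjusted p = 0.363). Secondary metabolite synthesis had 1 higher and 12 not passing (1 adjusted over the list alone; adjusted p = 0.803), the squalene-pathway gene *hpnD_2*.

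None of the following lists of regulatory, envelope and phage genes passed camera, and among all tested genes more fell than rose as well. Quorum sensing had 1 higher, 7 lower and 14 not passing (1 and 7 adjusted over the list alone; adjusted p = 0.31, shortened 1, 6 and 10), with *luxQ_1* (P39_1_00080) lower at -1.75. Cyclic di-GMP enzymes had 2 higher, 3 lower and 18 not passing (1 and 1 adjusted over the list alone; adjusted p = 0.904, shortened 1, 3 and 10), the diguanylate cyclase *dgcM* being lower at -2.54. Exopolysaccharide and cellulose had 3 lower and 19 not passing (3 adjusted over the list alone; adjusted p = 0.736, shortened 0, 3 and 10), with *acsD* at -1.45. Cell division and peptidoglycan had 12 higher, 7 lower and 44 not passing (13 and 7 adjusted over the list alone; adjusted p = 0.31), with *rlpA* (P39_1_02518) higher at 2.18 and *mpl* lower at -2.28. Phage, transposon and toxin-antitoxin genes had 6 higher, 2 lower and 13 not passing (6 and 2 adjusted over the list alone; adjusted p = 0.401, shortened 4, 1 and 6), the toxin gene *higB* being higher at 3.09. Of the named genes *nagZ*, *vgrG1_1*, *vgrG1_4*, *vgrG1_6*, *hpnD_2*, *rplD*, *atpB*, *sdhC*, *fabG_1*, *accA*, *fabV*, *cynT* and *ugpB* did not pass in at least 1 fit with a library left out. Where a symbol used here occurs on both contigs, only the copy meant had passed. In the lists of sugar and polyol, siderophore, universal stress, translation factor, sulfur and phosphate genes the median, the mean and the camera direction differed in sign. With library totals, of the 59 named genes that fell, 14 stayed lower and passed, 26 stayed lower without passing, among them *flhD*, *fliK*, *bfr*, *phaA* and *phaB*, and 19 turned higher without passing, among them *nagZ*, *xcpT*, *acsD*, *cydB*, *kynA*, *fadB*, *fabG_1*, *ugpB*, *hpf* and *vgrG1_4*.

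**Figure D4:**
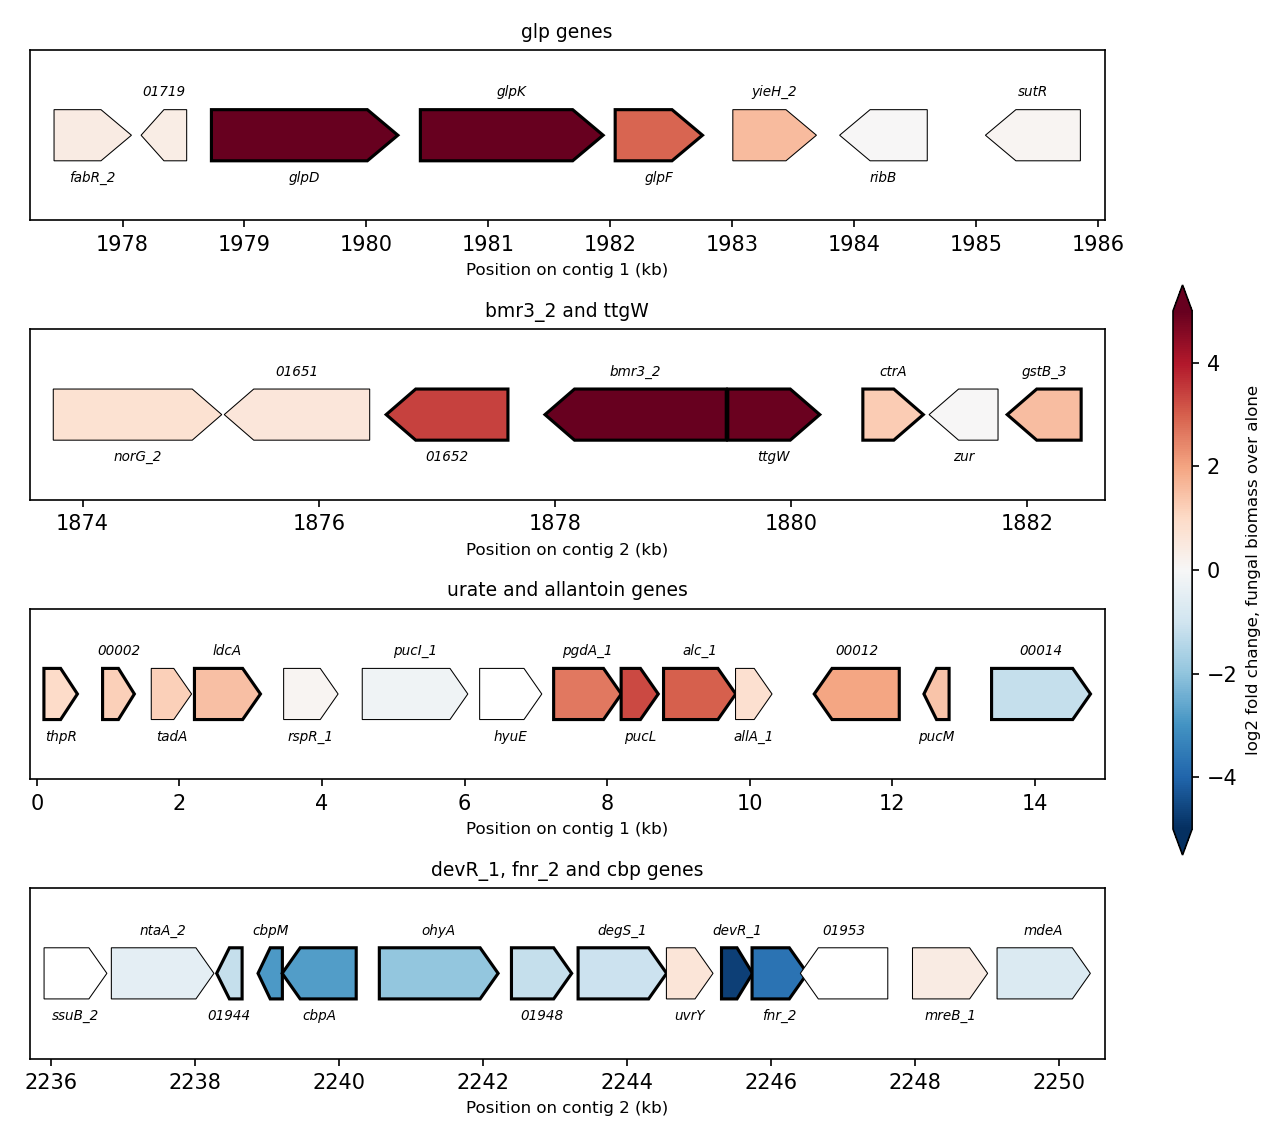
Maps of 4 regions chosen after the values were seen, with position in kb, an arrow per gene in its direction, colour for the log2 fold change (fungal biomass over alone, white where not tested) and a thick outline for an adjusted p under 0.05. glpD and glpK rose side by side, bmr3_2 and ttgW rose as a divergent pair, and devR_1 and fnr_2 fell next to each other. Beside glpK, glpF only just passed (edgeR adjusted p = 0.0492), at 0.266 CPM alone and 1.91 CPM with fungal biomass.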

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

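The alternatives that removed *ssrA*, thinned the counts, used reads recovered from the RLE values or shortened the lists were chosen only after the results were seen. The count of 1475 changed genes stayed within 1.5 times under RLE and upper-quartile factors, removal of the 10 most counted genes and no filter. It also did so under DESeq2 (1727), limma-voom, log2 RLE values and removal of *ssrA*. The fit that used replicate number as a block (1440 genes) shared 1351 genes. Recovered reads gave 1511 genes, but they equal the deposited counts. That fit repeats the main one on the 5256 genes above 0 in all 6 libraries and is no separate check. The count moved with library totals (2728 genes, 2671 of them higher). It moved too with limma on log2(FPKM + 1) (2927), log2(FPKM + 0.1) (2844) and log2(FPKM + 1) for genes with a mean FPKM of at least 1 (2995). FPKM values are scaled by library totals by their construction, and these totals include *ssrA*. A mean CPM of at least 20 tested only 1774 genes and called 970. Leaving out a library gave 809 to 1627 genes, with 809 without alone replicate 3, 874 without alone replicate 2 and 914 without fungal biomass replicate 2.

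Of 1315 genes changed at least 2-fold, library totals gave 2728, a mean CPM of at least 20 gave 710 and glmTreat against 1.5-fold, a stricter test by construction, gave 817. Leaving out a library gave 809 to 1528, with 871 without alone replicate 2 and 809 without alone replicate 3.

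The single list call was the least stable result. Library totals, the replicate block and the estimated correlation each gave 0 lists, fry gave 9 and the shortened lists gave 2, or 0 with an estimated correlation. Leaving out a library gave 0 to 3 lists, with 0 without alone replicate 1 or fungal biomass replicate 1, 2 without alone replicate 3 and 3 without fungal biomass replicate 3, which were amino acid biosynthesis, flagellum and motor, and ribosomal proteins (adjusted p = 0.0356, 0.0245 and 0.0245). The cause was not tested.

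Of the 95 named genes that passed, 69 passed under RLE factors, no filter, DESeq2, the replicate block and each library left out, 26 did not pass in at least 1 of these 10 alternatives, and 0 reversed. The 26 were *nagZ*, *degS_1*, *vgrG1_4*, *vgrG1_6*, *vgrG1_1*, *hpnD_2*, *luxQ_2*, *pdeN*, *rplD*, *ndh*, *atpB*, *cydB*, *bshA_2*, *sdhC*, *gcvA_4*, *kynA*, *fadD_1*, *fabG_1*, *accA*, *fabV*, *cynT*, *ugpB*, *intA*, *rlmB_2*, *ssrA* and P39_1_00155. The cyclic di-GMP gene *pdeN* passed in none of them. Library totals, applied to the named genes after the results were seen, turned 19 of the 59 lower genes higher and left 14 lower and passing. That scaling shifted the median of all genes upwards, so it is no test of the genes that rose.

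Depth outside *ssrA* was lower in the alone libraries. After all libraries were thinned to 3836710 counts outside *ssrA*, 1285 of 1474 called genes, or 87.18%, kept their call and sign, which argues against unequal depth as the source of most calls. In the simulation 25 of 100 2-fold changes were recovered. Far fewer genes changed there than were called here, which makes the Benjamini-Hochberg cutoff stricter. That share is therefore no measure of how many 2-fold changes were missed here, though smaller changes may still have been missed.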

Other observations

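The regions and groups of neighbours described here were chosen only after the values were seen, and so was the test of the share of neighbours in which the upstream gene changed more. Near the start of contig 1, several genes with urate or allantoin products rose. *pucL* rose from 4.53 to 46.6 CPM (mean of 3 libraries), with a log2 fold change of 3.32 and an edgeR adjusted p of 0.000744, and the allantoicase gene *alc_1* rose at 3.00. The hydroxyisourate hydrolase gene *pucM* rose at 1.42. The permease gene *pucI_1* (-0.20) and *allA_1* (0.81) did not pass. Their means of 1.18 and 3.38 CPM leave their direction open. The overlapping gene *pgdA_1* rose at 2.65, while the 8-oxoguanine deaminase gene P39_1_00014 fell at -1.17 and the allantoin permease gene *pucI* on contig 2 lay in a run that fell (-2.62 to -1.04). Next to *glpK*, the glycerol facilitator gene *glpF* had a log2 fold change of 2.92 but only 1.91 CPM with fungal biomass (adjusted p = 0.0492).

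The iron-sulfur assembly genes *iscU*, *iscS* and *iscR* rose at 1.41, 2.22 and 2.15, though the groups overlapped in *iscS* and *iscR*. Beside them *iscA* (1.26, adjusted p = 0.0532), *hscB* (1.00, adjusted p = 0.224), *hscA* (0.21) and *fdx_1* (-0.31, adjusted p = 0.518) did not pass. A run of 10 ribosomal protein genes from *rpsQ* to *rplC* fell, with a median of -1.57, and *rpsJ* beside it did not pass (0.37). Near *devR_1*, the curved DNA-binding protein gene *cbpA* fell from 4356 to 623 CPM and the oleate hydratase gene *ohyA* at -1.98. The hypothetical genes P39_1_03311 to P39_1_03315 fell with a median of -3.54.

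The higher share of *ssrA* in the alone libraries was weighed against a loss of short RNAs with fungal biomass. Genes of up to 400 bp had a median log2 fold change of -0.567 (95% bootstrap interval -0.809 to -0.314), above the bound of -1.34 set before the result was seen. The interval comes from draws of genes and does not cover variation between libraries. These values argue against poorer recovery of short genes as the whole source, but 120 of 288 such genes fell and 30 rose, and without ribosomal protein genes the median was -0.636. A smaller length effect may contribute, and coding length is not transcript length. Growth state, batch and RNA preparation stay open, since each is tied to the groups.

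Genes on contig 2 lay lower than those on contig 1 by -0.383 in median log2 fold change (95% bootstrap interval -0.447 to -0.308), and by -0.438 to -0.305 when each library was left out. The bootstrap intervals come from draws of genes and do not cover variation between libraries. Outside *ssrA*, contig 2 held 27.65% to 29.54% of the counts in the alone libraries and 23.42% to 24.7% with fungal biomass. Within 5 bins of mean CPM the gap was -0.403 (interval -0.493 to -0.332), which argues against a difference in expression level between the contigs as its source. On contig 1 the genes nearest to and farthest from *dnaA* differed by -0.0323 (interval -0.169 to 0.127), within -0.191, which argues against dosage along that contig. A difference in copy number between the contigs was not tested. A response of contig 2 genes to fungal material is a hypothesis only.

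Changes did not clearly shrink along same-strand neighbours. Among neighbours at most 50 bp apart with a call, the upstream gene changed more in 51.46% of 412 pairs (exact binomial p = 0.588), against 49.5% of 216 pairs at least 300 bp apart. The median log2 FPKM ratio of upstream over downstream gene rises as downstream signal is lost. Among neighbours at most 50 bp apart it was higher by 0.142 with fungal biomass, with ranges of 0.983 to 1.15 alone and 1.13 to 1.40. The ranges overlapped by 0.02, less than the bootstrap spread of that overlap (-0.0439 to 0.163), so the test left a difference in transcript integrity open. Requiring an overlap beyond its spread was added after the values were seen. Among neighbours at least 300 bp apart the ratio was lower with fungal biomass, at -0.619 to -0.299 against -0.223 to -0.106 alone, which was not tested.

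The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. Of these splits, 1 gave as many changed genes as the real split, itself, with 1475 genes against 0 as the highest other. For 2-fold changes it was again 1, with 1315 against 0. Every other split put libraries of both conditions in each group, which widened the spread within groups. Few gene calls were therefore to be expected there, and these contrasts with 0 say nothing about chance. For gene lists 5 splits gave as many, with 1 list in the real split and 3 as the highest other.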
